A study of Mus musculus with 2 samples.

How the data were processed

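Chromatin carrying trimethylated lysine 4 of histone H3 (H3K4me3) was immunoprecipitated and sequenced (ChIP-seq) from hindbrain of mouse embryos of strain B6NCrl at embryonic day 13.5. Per the labels, each sample pooled male and female embryos, and the 2 samples are biological replicates of 1 group. The design therefore holds no second condition, and no groups of samples were compared.

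The deposited files are 4 lists of peaks on assembly mm10, per the labels and the file headers. Replicate 1 and replicate 2 each have a list called against a control of their own. A pooled list was called on the reads of both replicates together, and a replicated list was derived from the pooled list and both replicates' lists, per the file headers. The aligner, the peak caller, their versions and thresholds, and the treatment of reads that map to several places are not given in the sources used here.

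For each peak the authors' lists give a display score, a fold enrichment, the −log10 of a p-value, the −log10 of a q-value and the position of the summit. The deposited score column sets how dark a peak is drawn and was not analysed. The deposited fold enrichment is a ratio over background: for 2000 peaks drawn from each list with a −log10 p of at least 10, the fold and p columns together gave a whole-number pileup within 0.01 for 100% of peaks, under fold = (pileup + 1) / (background + 1) and a Poisson tail for p. The lowest background recovered that way was 3.12 per base in replicate 1, 3.23 in replicate 2 and 6.35 in the pooled list, held by 65.2%, 40.9% and 62% of the drawn peaks. The deposited −log10 p and −log10 q columns were used only to rank or filter peaks within a list. These values are the authors' own per-peak values, and no value was compared across lists as a change. The total number of reads per sample is unknown, so no precision from read depth can be given.

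Gene starts were taken from GENCODE release M21 and sequence from GRCm38.p6, the same assembly as mm10. Every peak on chromosomes 1 to 19, X and Y ended within its chromosome. Peaks on unplaced scaffolds were left out of all gene-level steps. A protein-coding gene was called marked when a replicated peak overlapped the 1 kb either side of any start of its protein-coding transcripts, and unmarked when none did, even if another list had a peak there. Peaks closer than 1 kb were joined to domains, the breadth of a gene was that of its longest domain, and the broadest 5% of marked genes were called broad. A promoter was CpG-rich when the 500 bp either side of the 5'-most start had an observed to expected CpG ratio of at least 0.6 and at least 50% GC. Peaks were placed by midpoint in promoters (within 1 kb of a start of any gene), then exons, introns and intergenic sequence, and peaks more than 5 kb from all starts were called distal. Overlap meant at least 1 bp, and was compared with 100 random placements on the same chromosomes. Coordinates are 1-based.

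Marking and breadth of 40 gene lists, fixed before the data were examined, were tested with the two-sided Fisher's exact test against the other protein-coding genes (for breadth, the other marked genes), with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Log2 odds had 0.5 added to each cell. Across settings the direction of a list was read from the difference of the percentages, because the added 0.5 can turn the sign of the odds when all members of a small list are marked, a choice made after the values were seen. Hox coverage was the percent of bases under replicated peaks within 2 kb of a gene's starts, compared by a two-sided permutation test with 100000 resamples, and so was the log2 breadth of 2 pairs of lists. Genes are not independent replicates, and neighbours can share a domain: these p-values describe how genes fall in these peak lists, not the spread between embryos. Intervals are 95% Wilson intervals over genes or peaks and cover counting error only. On simulated lists over 21853 genes with 5 lists changed 8-fold in odds, the list test recovered 98.4% of changed lists and called 0.941% of unchanged ones, over 50 simulations. There, genes were drawn independently, both CpG classes had similar marking rates, unlike here, and the changed lists had 19 to 1092 members. The breadth test was not simulated. These rates therefore need not hold for small lists, for genes that share a domain or for breadth. The permutation test called 4% of 200 null draws and 100% of draws shifted by 2 SD. Those draws were independent, normally distributed and in groups of equal size, with fewer resamples than used here. Their rates therefore need not hold for Hox coverage, which is bounded, or for genes that share a peak or domain.

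Named genes followed a rule fixed beforehand: per list, up to 4 marked members with the broadest domains and up to 4 unmarked members first in list order (all where 5 or fewer), the 15 genes with the broadest domains, the 10 promoter peaks of highest fold, all Hox genes, Xist, the Y-linked list, the 5 broadest genes marked in only 1 replicate, for each replicate, and the 5 distal peaks of highest fold. Symbols of 2 list members were not found in the annotation. Alternatives covered the overlap required, stricter peak thresholds, window and joining distances, the 5'-most start alone, CpG-rich promoters alone, the pooled list and each replicate's own list. The direct test of hindbrain against forebrain factors, and the count of each domain once, were added after the list values had been seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.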

Results

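H3K4me3, a histone mark of active and poised gene starts, was profiled in the hindbrain of mouse embryos at embryonic day 13.5, when the tissue holds neural progenitors, young neurons and the early cerebellum. There were 2 biological replicates of 1 group. Replicate 1 had 31140 peaks covering 41.9 Mb and replicate 2 had 29653 peaks covering 39.5 Mb. The authors' pooled list held 31840 peaks and their replicated list 24431 peaks covering 43.2 Mb, of which 24412 lay on chromosomes 1 to 19, X and Y (mm10). With a single group, the questions the data can answer are how far the replicates share peaks, where the peaks lie, and which genes carry them.

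The replicates shared nearly all strong peaks and differed at weak, narrow ones. Of replicate 1's peaks, 80.6% (95% interval 80.1 to 81.0) overlapped a peak of replicate 2, and 88.4% (88.1 to 88.8) of replicate 2's peaks overlapped one of replicate 1. Randomly placed peaks gave 2.84% and 2.995%. The 6050 unshared peaks of replicate 1 had a median width of 240 bp and a median fold of 3.01, against 1352 bp and 22.1 for its shared peaks. In replicate 2 the 3425 unshared peaks had a median width of 228 bp and fold of 2.89, against 1190 bp and 16.5. Each list was ranked by its own fold and split into 10 bins of equal size. In replicate 1, 33.8% of the weakest bin was shared, 98.7% of the fifth bin, and 100% of the stronger bins. In replicate 2 the share was 54.2% in the weakest bin, 99.97% in the fifth and 100% in the stronger bins. Requiring 50% overlap of both peaks lowered the shares to 70.4% and 73.9%.

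**Figure D1:**
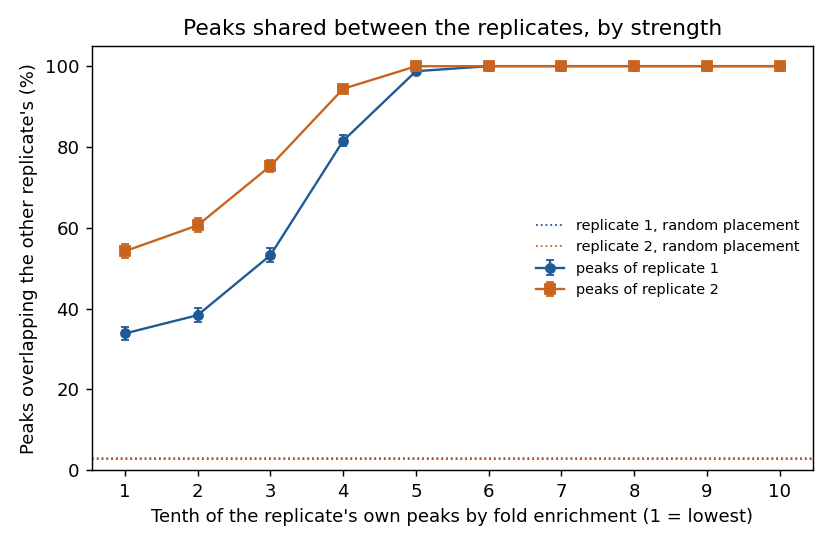
Percent of each replicate's peaks that overlap the other replicate's (y axis) by bin of its own fold enrichment, from the weakest to the strongest (x axis), with 95% Wilson bars and dotted lines for random placement. The weakest bin was shared at 33.8% in replicate 1 and 54.2% in replicate 2, and all bins above the fifth at 100% in both.

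The replicated list kept the strong part of the pooled list. It held 76.7% of pooled peaks, with a median width of 1495 bp and fold of 24.6, and the 7409 peaks not kept had medians of 239 bp and 2.58. Of the kept peaks, 94.6% overlapped peaks of both replicates, 1282 overlapped peaks of only 1 and 44 overlapped none.

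Replicated peaks lay mainly at gene starts. Promoters held 63.6% of peaks (63.0 to 64.2) and 76.7% of peak bases, against 5.88% of the genome, a ratio of 10.8. Introns held 17.2% of peaks against 37.3% of the genome, intergenic sequence 14.1% against 53.7%, and exons 5.10% against 3.09%. Promoter peaks had a median width of 1999 bp and fold of 43.3, intron peaks 644 bp and 4.56. The promoter share was 54.2% in the pooled list and 90.3% among replicated peaks at or above the list's median −log10 p.

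Among promoter peaks, Eif3b, a translation initiation factor subunit, had the highest fold, 80.4, at a domain on chromosome 5 from 140417905 to 140421666. The shared promoter of Spata2 and Rnf114 followed at 80.0, then Hnrnpr, an RNA-binding protein, at 79.7 and Msl1, a subunit of a histone acetyltransferase complex, at 79.6. These domains were 3762, 3242, 3577 and 5375 bp broad, below the 5748 bp that bounds the broadest 5%. Ssbp3, also among the 10 highest at a fold of 79.2, had a domain of 7112 bp, above that bound.

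A further 4202 replicated peaks, 17.2% (16.7 to 17.7), lay more than 5 kb from all annotated starts. They were narrower and weaker than peaks within 1 kb of a start, with a median width of 634 bp and fold of 5.31 against 2031 bp and 43.0. The strongest distal peaks had a higher fold than the median promoter peak. An intergenic peak on chromosome 9 from 32031334 to 32034681 had a fold of 65.0, and the nearest protein-coding start, that of Arhgap32, lay 81455 bp away. A peak of 12141 bp on chromosome 15 from 85669703 to 85681843, inside an intron of the non-coding gene Lncppara and 53721 bp from Ppara, had a fold of 61.9. Others were in an intron of Ldb3 on chromosome 14 from 34548108 to 34549855 (fold 58.9), near Cldn9 on chromosome 17 from 23699083 to 23700622 (58.4) and near Fcgr4 on chromosome 1 from 171037672 to 171038777 (58.1). Among peaks at or above the median −log10 p the distal share was 2.20%.

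Of 21853 protein-coding genes, 14381 were marked, 65.8% (65.2 to 66.4). Gene calls differed little between replicates: 14442 genes were marked in replicate 1 and 14384 in replicate 2, and 14303 in both, which is 98.5% of those marked in either. Only 139 genes were marked in replicate 1 alone and 81 in replicate 2 alone. Among the broadest of these, Cyp27b1 and Apold1 of replicate 1 alone had replicated folds of 3.13 and 3.39. Ptpn6 and AC141477.1 of replicate 2 alone had 48.8 and 62.7. Such a call need not mean that the other replicate lacked a peak nearby, since a peak can end outside the 1 kb window. CpG-rich promoters were marked in 9756 of 9848 genes, 99.1% (98.9 to 99.2), and the other promoters in 4625 of 12005, 38.5% (37.7 to 39.4), a log2 odds of 7.39 with a Fisher's exact p below the smallest number double precision can hold. Marked genes had a median breadth of 2433 bp.

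The lists share members, so that their calls are not separate evidence: 16 of the 35 dorsoventral factors, 11 of 23 progenitor genes, 6 of 14 granule lineage genes and 3 of 20 mesenchymal genes are also in another list. So are 5 of 14 serotonergic, 6 of 14 noradrenergic and visceral motor, 4 of 16 Purkinje and 5 of 18 neural crest genes. Among the 40 gene lists, 20 were marked more often than other genes, 9 less often and 11 did not pass the test. All members of 10 lists were marked, among them the 28 hindbrain patterning factors, 35 dorsoventral neuron fate factors of the hindbrain, 23 neural progenitor genes, 30 genes of postmitotic neurons, 40 axon guidance genes, 32 cell cycle genes and 36 subunits of mitochondrial complex I. Among CpG-rich promoters 99.1% of genes were marked, so that no list of these sizes could have passed as more often marked, and none did. In that setting 2 lists were marked less often: replication-dependent histones and germ line genes. Raising the threshold to the median −log10 p left 12 lists more often and 21 less often marked. There, 22.9% of dorsoventral factors were marked against 55.7% of other genes, so that their direction turned, and for hindbrain patterning factors the share was 75% and no longer past the test. Marking also turned there for forebrain and midbrain factors, histones, neural crest genes and protocadherins, and no longer passed for granule and Purkinje lineage genes.

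**Figure D2:**
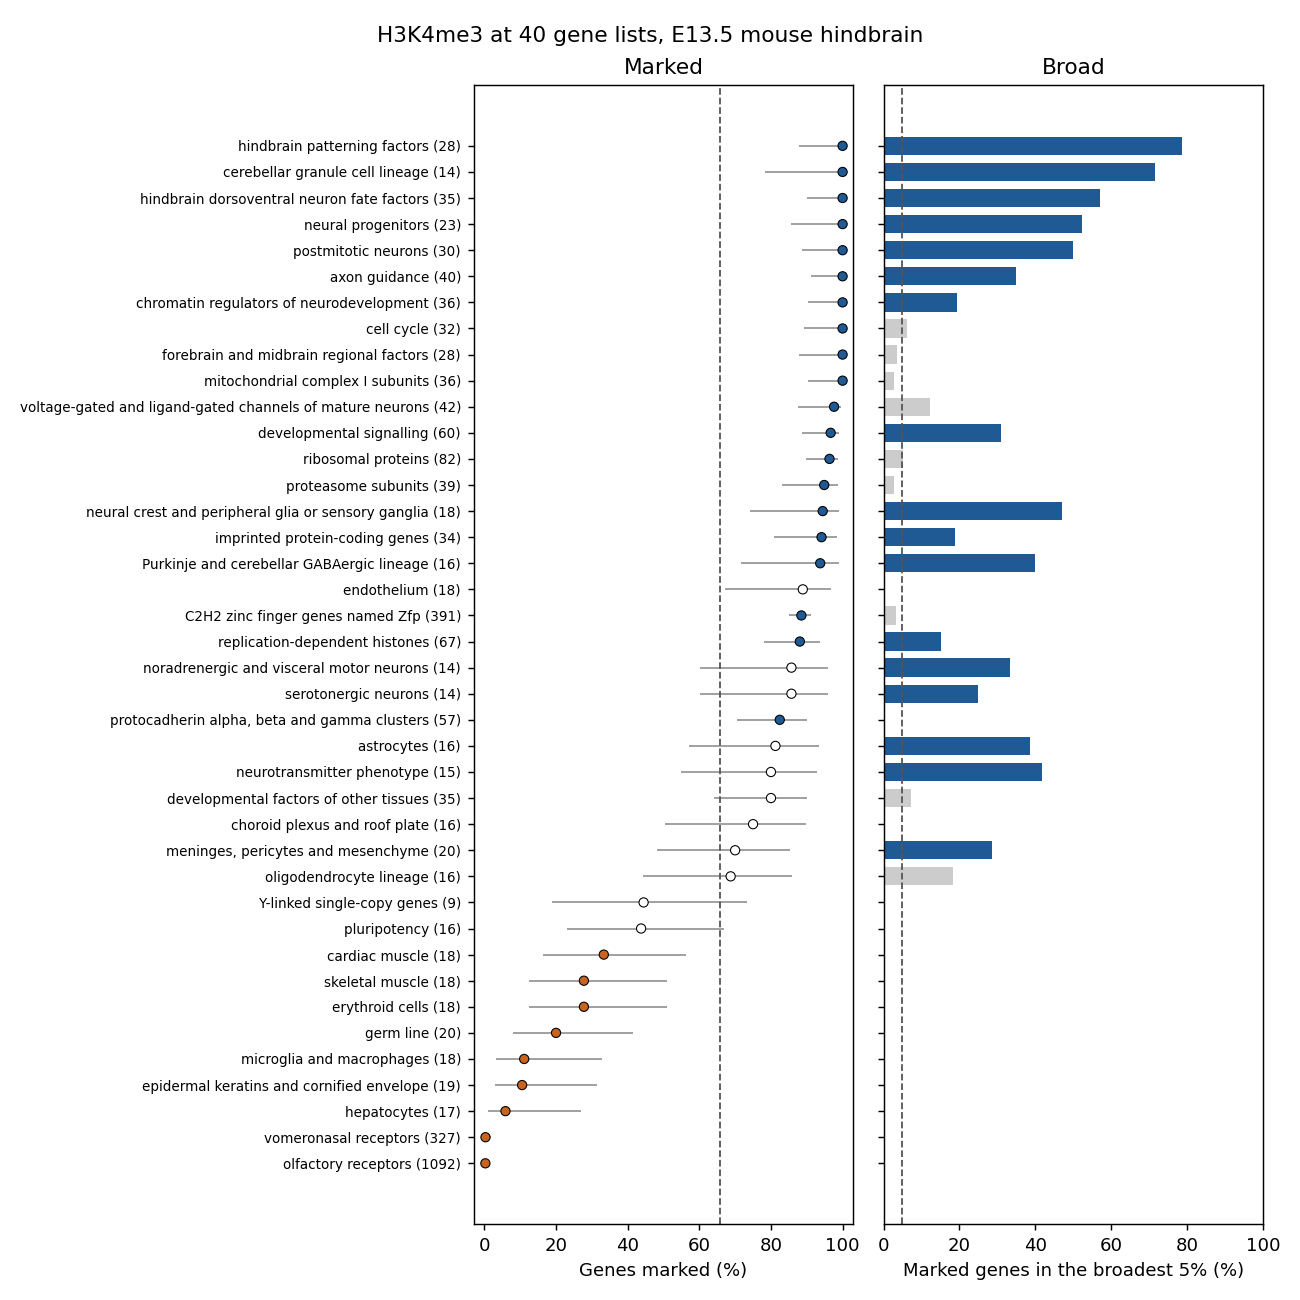
Left, percent of each list's genes that are marked (x axis), with 95% Wilson bars, the member count after each name and a dashed line at 65.8% for all genes. Blue points were more often and orange points less often marked at an adjusted p under 0.05, and white points were neither. Right, percent of marked genes in the broadest 5%, with lists past the test in blue and a dashed line at 5%: hindbrain patterning factors reached 78.6%.

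Lists also differed in the breadth of their domains. Of the lists, 17 were more often in the broadest 5% of marked genes and none less often. Most lists were too small to pass as less often broad: with 0 of 47 marked genes broad, protocadherins gave an unadjusted p of 0.174 (Fisher's exact test). Hindbrain patterning factors led, with 22 of 28 broad (78.6% against 4.86% of other marked genes, adjusted p = 2.04e-22, Fisher's exact test) and a median breadth of 11454 bp. These 22 genes do not stand alone, since the 28 members lie in 22 domains. Hoxb2, Hoxb3 and Hoxb4, which pattern the rhombomeres, shared a domain of 78152 bp on chromosome 11 from 96277332 to 96355483 with Hoxb5 to Hoxb8, the broadest in the genome. Hoxa1 to Hoxa6 shared one of 58302 bp on chromosome 6 from 52155721 to 52214022. Joining made these breadths sensitive to small gaps: Hoxa1's domain was 57843 bp in replicate 1 and 30188 bp in replicate 2, and Hoxb2's 8194 bp and 78385 bp. Outside the Hox clusters, chosen after their values were seen, the broadest domains lay over Nr2f2 (26016 bp), Ebf3 (25607 bp), Meis2 (24947 bp) and the Zic1 and Zic4 pair (23106 bp).

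Neuron fate factors were also broad. Of the 35 dorsoventral factors 20 were broad (adjusted p = 2.42e-16, Fisher's exact test), with a median breadth of 7646 bp. Lhx1 and Lhx5, of inhibitory and Purkinje neurons, had domains of 22057 and 17982 bp, Gata3, of serotonergic neurons and ventral interneurons, 18709 bp, and Pax3, of dorsal progenitors, 17477 bp. Cerebellar granule lineage genes were broad in 10 of 14 (adjusted p = 7.77e-10, Fisher's exact test), led by Zic1 and Zic4, Meis1 (15561 bp) and Pax6 (15117 bp). Purkinje and cerebellar GABAergic genes were marked in 15 of 16 and broad in 6 (adjusted p = 0.000233, Fisher's exact test). Bcl11a and Pax2 had domains of 18672 and 12750 bp, and the late Purkinje gene Pcp2 was unmarked. Lhx1 and Lhx5, counted above as dorsoventral factors, are also among the 6 broad genes, and Pax2 is also in the patterning list.

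Among genes of transmitter phenotypes, several transcription factors and transporters and the synthesis enzyme Gad1 were broad. Some other synthesis enzymes and the transporter Slc17a8 were unmarked, and no contrast between these kinds of gene was tested. Slc17a6, the glutamate transporter of hindbrain neurons, had a domain of 13642 bp, Slc32a1, the vesicular GABA and glycine transporter, 12544 bp, Gad1 12082 bp and the glycine transporter Slc6a5 10373 bp. In that list 12 of 15 genes were marked and 5 broad (adjusted p = 0.000732, Fisher's exact test), and Slc17a8, Th and Tph2 were unmarked. Serotonergic genes were marked in 12 of 14, with Lmx1b at 17124 bp and Gata2 at 10396 bp, and without Tph2 and Ddc. Their 3 broad members, Gata2, Gata3 and Lmx1b, are all also in the dorsoventral list. They gave an adjusted p of 0.0461 (Fisher's exact test), an excess of 20.01 points over other marked genes. The call was lost among CpG-rich promoters alone, among peaks at or above the median −log10 p and with the broadest 10%, although the excess there was 28.3, 35.01 and 23.3 points. Noradrenergic and visceral motor genes were marked in 12 of 14 and broad in 4 (adjusted p = 0.00687, Fisher's exact test). Tbx2, Isl1 and Phox2b had domains of 15022, 9457 and 7646 bp. Isl1 and Phox2b are also in the dorsoventral list. In replicate 2's own list Tbx2 had 8563 bp and Isl1 3334 bp, the latter below the bound. Dbh and Th, enzymes of noradrenaline synthesis, were unmarked. With only touching peaks joined, none of the noradrenergic list's genes was broad, nor among peaks at or above the median −log10 p, and with peaks under 3 kb apart joined the call was lost.

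Progenitor genes and neuronal genes were both often broad. Of 23 progenitor genes 12 were broad (adjusted p = 1.44e-09, Fisher's exact test), with Sox2 at 17647 bp, Msi1 at 10041 bp and the Notch effector Hes1 at 8457 bp. Of 30 genes of postmitotic neurons 15 were broad (adjusted p = 2.76e-11, Fisher's exact test), including Myt1l at 13864 bp, Elavl4 at 11698 bp, Celf4 at 9284 bp and Scrt1 at 9107 bp. Axon guidance genes were broad in 14 of 40 (adjusted p = 2.16e-08, Fisher's exact test), with the guidance ligand Efnb2 at 8786 bp and the receptors Nrp1, Nrp2 and Plxna2 at 8352, 8274 and 7516 bp. Developmental signalling genes were marked in 58 of 60 and broad in 18 (adjusted p = 1.44e-09, Fisher's exact test). Ptch1, the Sonic hedgehog receptor, reached 16011 bp, Cyp26b1, which degrades retinoic acid, 12244 bp, Wnt5a 11352 bp and the retinoic acid receptor Rara 10851 bp, and Cyp26c1 and Wnt8b were unmarked. Cyp26c1 had peaks in the pooled list and in both replicates' own lists.

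Factors of the forebrain and midbrain were all marked, mostly by domains that were not broad. The median over all marked genes was 2433 bp (lower quartile 1778 bp), and many of these factors lay below that quartile. All 28 carried a replicated peak (adjusted p = 2.36e-05, Fisher's exact test). Their median highest fold was 10.2, against medians of 54.8 over marked genes with CpG-rich promoters and 34.0 over the other marked genes. Their median breadth was 2045 bp, and only 1 was broad (Gsx1, 6107 bp). That is 3.57%, against 5.01% of other marked genes. The difference turned direction in replicate 1's own list, among CpG-rich promoters, with peaks under 3 kb apart joined and with the broadest 10%. It passed the test in no setting, but with 28 genes a lower broad share could not have passed in the main setting. Neurod6, Otx2 and Satb2 had domains of 5412, 5296 and 4677 bp, and Otx2 is also in the choroid plexus and roof plate list. Expression was not measured, so members of the forebrain and midbrain list, Gsx1 included, may also be active in the hindbrain. On the log2 scale hindbrain patterning factors were broader by 2.74 in the mean (28 against 28 genes, SD 1.74 and 1.01, permutation p = 2e-05, the smallest the resampling can give). With each domain counted once the difference was 2.17 (22 against 28), and without Hox genes it was 1.92 (18 against 28), both at the same smallest permutation p. Among peaks at or above the median −log10 p, only 7.14% of forebrain and midbrain factors were marked, which turned the direction of their marking.

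**Figure D3:**
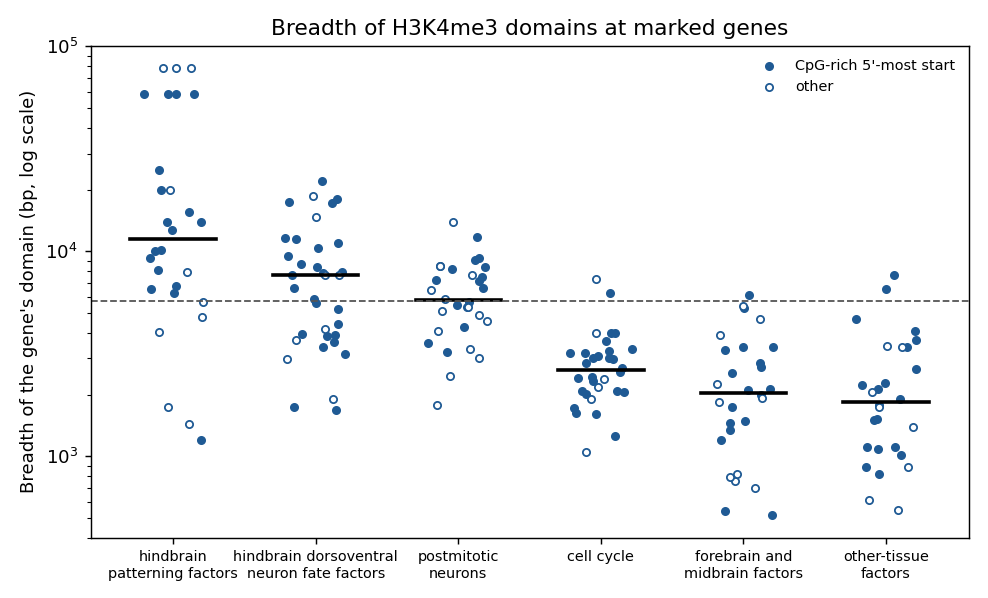
Breadth in bp (y axis, log scale) of the domain at each marked gene of 6 lists, with filled points for a CpG-rich 5'-most start, bars for medians and a dashed line at 5748 bp, the bound of the broadest 5%. Medians run from 11454 bp for hindbrain patterning factors to 2045 bp for forebrain and midbrain factors and 1837 bp for factors of other tissues.

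Genes of cell division, translation, respiration and protein turnover were marked more often than other genes. Cell cycle genes were marked in 32 of 32 and broad in 2 (Ccnd2, 7283 bp, and Ccnd1, 6227 bp). Ribosomal protein genes were marked in 79 of 82 with 4 broad, and the unmarked members were the tissue-restricted copies Rpl10l, Rpl39l and Rpl3l. Complex I subunits were marked in 36 of 36, with 1 broad, and proteasome subunits in 37 of 39, with 1 broad, the thymus and testis subunits Psmb11 and Psma8 being unmarked. None of these 4 lists passed the test for breadth. Chromatin regulators of neurodevelopment were marked in 36 of 36 and broad in 7 (adjusted p = 0.00597, Fisher's exact test), with Setd1b at 14710 bp and Kdm6b at 12793 bp. In replicate 1's own list the broad share was 13.9%, down from 19.4%, and that call was lost. It was also lost at or above the median −log10 p, among CpG-rich promoters, with peaks under 3 kb apart joined and with the broadest 10%. Replication-dependent histones were marked in 59 of 67 and broad in 9 (adjusted p = 0.00713, Fisher's exact test), but their genes share domains, such as the 7272 bp over Hist1h4h, Hist1h2af and Hist1h3g. Counting each domain once ended that call, as did peaks at or above the median −log10 p, joining only touching peaks and the broadest 10%. The excess was 10.3 points, and 3.83, 12.4, 1.78 and 5.26 points in those settings. Histone copies are nearly identical, so their marking is uncertain. Zfp genes were marked in 346 of 391, more often than others, with 11 broad.

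Markers of other cell types in or next to the tissue varied. Neural crest and sensory ganglion genes were marked in 17 of 18 and broad in 8 (adjusted p = 3.09e-06, Fisher's exact test), with Tfap2a at 12936 bp, Tfap2b at 10046 bp and Foxd3 at 9753 bp, and Plp1 unmarked. Their marking no longer passed with the 5'-most start only. Of these 18 genes 5 are also in another list, among them Isl1 (9457 bp, broad), a dorsoventral factor of the hindbrain. The excess of broad genes therefore need not come from crest or ganglion cells. Astrocyte genes were marked in 13 of 16 and broad in 5 (adjusted p = 0.00104, Fisher's exact test): Nfib, Nfia, Fgfr3 and Sox9, which progenitors also use, had domains of 19531, 9915, 6677 and 6523 bp, while Gfap, Aqp4 and S100b were unmarked. The call on astrocyte breadth was lost with peaks under 3 kb apart joined. Of meningeal and mesenchymal genes 14 of 20 were marked, and 4 were broad (Zic1, Foxc1, Prrx1 and Foxc2; adjusted p = 0.0111, Fisher's exact test), a call lost in replicate 2's own list, where the broad share was 14.3% against 28.6%. That call was also lost at or above the median −log10 p, with only touching peaks joined, with peaks under 3 kb apart joined and with the broadest 10%. The excess was 23.6 points, and 28.3, 9.29, 9.29 and 18.6 points in those settings. Zic1 is also in the granule lineage list. Col3a1, Lum and Dcn of the same list were unmarked. Endothelial genes were marked in 16 of 18, just outside the threshold (adjusted p = 0.0604, Fisher's exact test), and in replicate 1's own list all of them were, which passed. Their marking also passed in the pooled list, did not pass in replicate 2's own list, and turned direction at or above the median −log10 p. Kdr had a domain of 4085 bp. Oligodendrocyte genes were marked in 11 of 16, with Pdgfra at 9009 bp and Olig2 at 6606 bp (4339 bp in replicate 2), and the myelin genes Mag, Mog, Mobp, Plp1 and Opalin unmarked. Choroid plexus and roof plate genes were marked in 12 of 16, without Ttr, Aqp1, Folr1 and Kcne2.

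The 9 lists marked less often were of microglia, erythroid cells, hepatocytes, skeletal and cardiac muscle, germ line, keratins, and olfactory and vomeronasal receptors. Microglial genes were marked in 2 of 18, Fcgr3 and Tmem119, at folds of 7.34 and 3.81 (adjusted p = 6.96e-06, Fisher's exact test). Erythroid genes were marked in 5 of 18 (adjusted p = 0.00275, Fisher's exact test): Tal1, Gypa, Klf1, Epor and Nfe2, while the globin genes Hba-a1, Hba-a2, Hba-x and Hbb-bt were not, near-identical copies among them being uncertain. Hepatocyte genes were marked in 1 of 17 (Apoh), keratin and cornified envelope genes in 2 of 19 (Lor and Krt10), germ line genes in 4 of 20 (Zpbp, Dazl, Tdrd1 and Ddx4), skeletal muscle genes in 5 of 18 and cardiac genes in 6 of 18, each list past the test. Only 5.56% of erythroid, 11.1% of skeletal and 16.7% of cardiac genes had CpG-rich promoters. Their marked shares, 27.8%, 27.8% and 33.3%, lay closer to the 38.5% of all genes without such promoters than to 65.8%. Microglial, hepatocyte and keratin shares, 11.1%, 5.88% and 10.5%, lay further below it. Lists were not compared within that class, so promoter composition cannot be told apart from tissue. Olfactory receptors were marked in 3 of 1092 and vomeronasal receptors in 1 of 327. Pluripotency genes, marked in 7 of 16 without Pou5f1 and Nanog, did not pass (adjusted p = 0.09, Fisher's exact test). They passed as less often marked at or above the median −log10 p, within 500 bp and with the 5'-most start only. Among CpG-rich promoters their direction turned. Developmental factors of other tissues were marked in 28 of 35 (adjusted p = 0.133, Fisher's exact test) and 2 were broad, Foxf2 at 7701 bp and Shox2 at 6526 bp. In the replicates' own lists the marked share was 85.7% and 82.9%, and in the pooled list 88.6%, past the test as more often marked in all 3. At or above the median −log10 p it was 2.86%, which turned the direction. Tbx5, Pdx1, Hand1 and Tbx4 were unmarked. Among genes called unmarked, Slc17a8, Psma8, Ttr and Pdx1 had a peak in the pooled list alone, Ddc in replicate 1's list alone, and Col3a1 and Tbx4 in both of these lists.

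Marking over the Hox clusters, whose genes are ordered along the chromosome as their domains are along the body axis, fell from low to high paralogue groups. Replicated peaks covered 84.3% ± 21.3 (SD) of the bases within 2 kb of the starts of the 12 genes of groups 1 to 4, 74.3% ± 30.1 in the 11 genes of groups 5 to 8 and 13.6% ± 18.5 in the 16 genes of groups 9 to 13. Groups 1 to 4 exceeded groups 9 to 13 by 70.7 points (permutation p = 2e-05, the smallest the resampling can give). Means per replicate for groups 1 to 4 were 82.2% and 80.2%, and for groups 9 to 13 they were 13.9% and 14.96%. Hoxa1, Hoxa2, Hoxb3, Hoxb4, Hoxa5, Hoxb5 and Hoxb7 were covered at 100%. Hoxb1 was the low exception among the first groups, at 35.7% with a fold of 5.32, and Hoxd1 had 50.4%. Hoxb9 was the high exception among the last groups, at 68.5%. The drop came between Hoxa6 (97.9%) and Hoxa9 (7.83%) in HoxA, and between Hoxc5 (78.8%) and Hoxc8 (12.3%) in HoxC. Of the 16 genes of groups 9 to 13, 9 were marked in the replicated list, 12 in each replicate's own list and 11 in both of those, Hoxc9 and Hoxc10 among the latter. At Hoxc9 and Hoxc10, however, the peaks of replicate 1 and replicate 2 did not overlap each other. Their folds were 2.67 and 3.31 at Hoxc9 and 2.91 and 3.55 at Hoxc10.

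**Figure D4:**
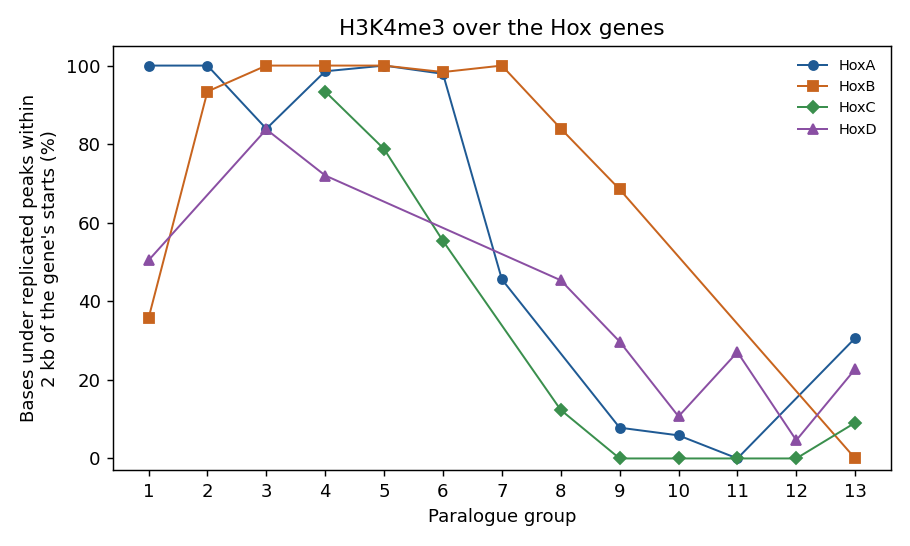
Percent of bases under replicated peaks within 2 kb of the starts (y axis) of each Hox gene by paralogue group (x axis), 1 line per cluster. Coverage averages 84.3% in groups 1 to 4 and 13.6% in groups 9 to 13, with Hoxb1 at 35.7% and Hoxb9 at 68.5% off that trend.

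**Figure D5:**
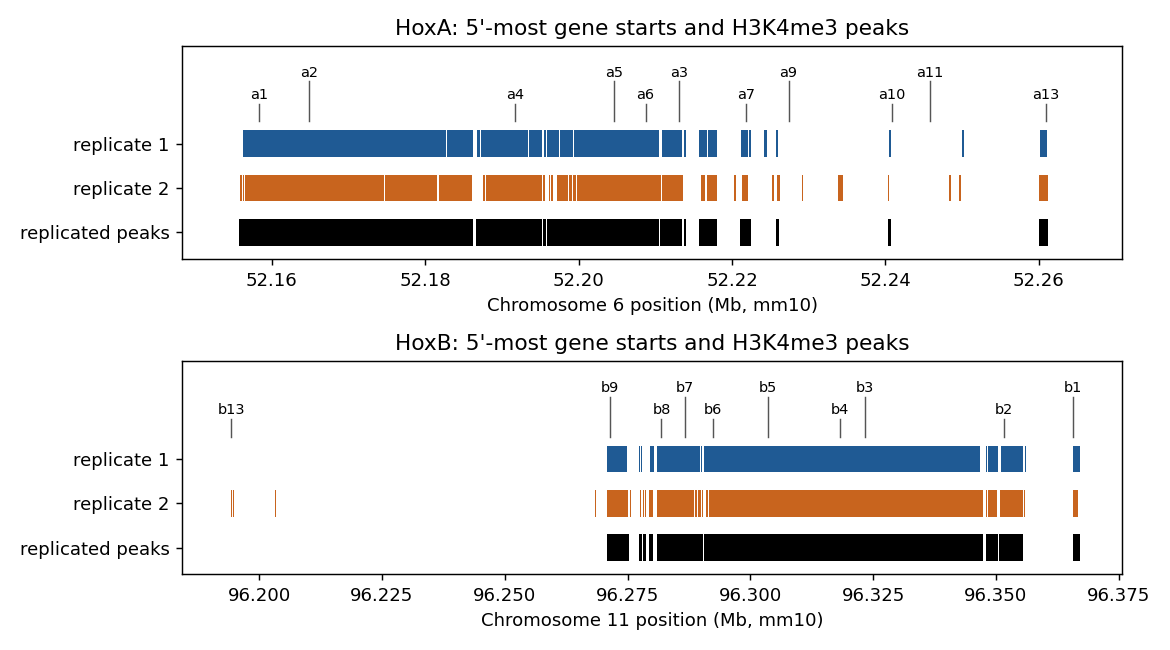
Peaks of replicate 1, replicate 2 and the replicated list (rows) over HoxA and HoxB against position in Mb (x axis, mm10), with ticks at the 5'-most start of each gene. Peaks cover most of the 58302 bp from Hoxa1 to Hoxa6 and the 78152 bp from Hoxb8 to Hoxb2, and are sparse beyond Hoxa7 and Hoxb9.

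Genes of both sexes were marked, and the samples pooled male and female embryos. Xist, transcribed from the inactive X chromosome, had peaks in both replicates and a replicated fold of 17.0 on the X chromosome between 103480408 and 103483868. Ddx3y, Eif2s3y, Kdm5d and Uty on the Y chromosome were marked at folds of 14.7, 12.8, 17.3 and 19.6, and Usp9y, Uba1y, Zfy1, Zfy2 and Sry were not (adjusted p = 0.315 for the list, Fisher's exact test). Imprinted genes were marked in 32 of 34 and broad in 6 (adjusted p = 0.0114, Fisher's exact test), with Gnas at 10249 bp. The excess over other marked genes was 13.8 points, and 23.2 in replicate 1's own list. The call was lost with only touching peaks joined and with peaks under 3 kb apart joined. Genes for channels and receptors of mature neurons were marked in 41 of 42, with Gabra6 unmarked, and their 5 broad members, 12.2%, did not pass the test (adjusted p = 0.117, Fisher's exact test). In replicate 1's own list the broad share was 7.32%, and in the pooled list the direction turned. With each domain counted once, 6 of 41 domains were broad, which passed the test (adjusted p = 0.0386, Fisher's exact test). Clustered protocadherins, close copies of one another, were marked in 47 of 57 at a median fold of 4.90, with none broad. In replicate 2's own list 77.2% were marked, against 82.5% in the replicated list, and their marking no longer passed.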

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

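The tests of explanations for unshared peaks were chosen after the result was seen. Peaks on unplaced scaffolds, which no gene-level comparison uses, numbered 19 in the replicated list, 26 in replicate 1 and 27 in replicate 2. They are given only because the comparisons leave them out, and no expected number was available to set them against. Their folds in the replicated list ran from 1.34 to 39.3.

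Peaks called in 1 replicate and not in the other had no biological explanation that the design can test. Background placed evenly at random over the genome as their only source is argued against by position, since 24.0% of the unshared peaks of replicate 1 and 23.2% of those of replicate 2 lay at promoters, which make up 5.88% of the genome. Background that itself favours promoters was not tested, and for the unshared peaks away from promoters the values decide nothing. Signal near the calling threshold stays open. Of peaks with a −log10 q of at least 10, at most 0.218% in either replicate lacked a partner (41 of 18819 in replicate 1 and 4 of 18304 in replicate 2), but the sharing by fold had already shown that strong peaks are shared, so this value could not have come out otherwise. Read totals are unknown, and the lowest background recovered from the peak values was 1.03 times as high in replicate 2 as in replicate 1, which does not point to greater depth in replicate 1, the one with more unshared peaks.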

How the results depend on the processing

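Each domain counted once and all settings of the direct breadth comparison were chosen after seeing the data. Read depth is unknown, so what it limits cannot be stated. The settings changed what counts as a peak, a promoter or a domain. The cause of the changes was not tested except where a setting's construction gives it. The direct breadth comparison kept its direction and its side of the threshold in the 10 settings tried, from 1.92 to 2.83 (2.35 at or above the median −log10 p, on 21 against 2 genes), as did CpG content in 7 (log2 odds 5.40 to 7.65) and Hox coverage in 7 (54.5 to 71.1 points).

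Shared peaks moved from 80.6% and 88.4% in replicates 1 and 2 to 70.4% and 73.9% with 50% overlap of both peaks, to 94.1% and 99.6% among peaks at or above each list's median −log10 p, and to 91.6% and 96.0% at a −log10 q of at least 5. Pooled peaks kept were 100% at or above the median −log10 p. Promoter shares were 54.2% in the pooled list, 56.0% to 58.2% in single replicates, 90.3% at or above the median −log10 p, 50.9% within 500 bp and 74.6% within 2500 bp. Distal shares were 19.5% in the pooled list, 16.8% to 17.8% in single replicates, 2.20% at or above the median, 25.8% beyond 2 kb, 11.7% beyond 10 kb and 27.1% from coding starts only. Marked genes were 66.5% in the pooled list, 55.6% at or above the median, 66.8% within 2500 bp and 63.1% with the 5'-most start only. Lists more and less often marked numbered 12 and 21 at or above the median, and 0 and 2 among CpG-rich promoters.

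For single lists, values are the list's percent minus that of other genes, in points. Of 383 comparisons of a called list with an alternative, 324 kept direction and call and 15 reversed. In the pooled list, marking passed the test for endothelium (33.5), mesenchyme (23.5) and other-tissue factors (22.1), and breadth for oligodendrocyte genes (22.3). Breadth turned there for choroid plexus (2.69), erythroid genes (14.999), protocadherins (2.41) and mature channels (-0.129), none of them called in the main setting.

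Over the replicates' own lists, marking of endothelium was 17.5 to 33.9, of other-tissue factors 17.1 to 19.7 and of protocadherins 11.4 to 19.9. Breadth was -1.44 to 2.14 for forebrain and midbrain factors, -1.22 to -1.21 for ribosomal proteins, 9.29 to 21.7 for mesenchyme, -5.01 to 3.33 for choroid plexus and 8.90 to 11.7 for chromatin regulators.

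At or above the median −log10 p, marking lost its call for hindbrain patterning (19.4), granule (15.8) and Purkinje genes (13.1). Direction turned for dorsoventral factors (-32.8), serotonergic (-19.9) and noradrenergic genes (-34.2), forebrain and midbrain factors (-48.6), histones (-21.4), oligodendrocyte (-30.7) and astrocyte genes (-5.65), endothelium (-27.9), mesenchyme (-40.7), neural crest (-5.65), choroid plexus (-30.7), other-tissue factors (-52.9) and protocadherins (-50.5). Pluripotency (-36.9) and Y-linked genes (-55.7) passed. Breadth lost its call for serotonergic genes (35.0), histones (12.4), mesenchyme (28.3) and chromatin regulators (8.92). Breadth turned for noradrenergic genes (-5.001), cell cycle (-5.01), ribosomal proteins (-2.48), oligodendrocyte genes (-5.002) and other-tissue factors (-5.0004). Microglial and Y-linked genes gave no breadth value there.

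Windows changed few lists. Pluripotency passed as less marked within 500 bp (-27.8) and other-tissue factors as more marked within 2500 bp (21.8). With the 5'-most start only, oligodendrocyte genes turned (-0.631), neural crest lost its call (14.7) and pluripotency passed (-38.2).

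Among CpG-rich promoters nearly all genes are marked, which leaves little to differ. Marking lost its call at 0.936 for hindbrain patterning, forebrain, progenitor, neuron, channel and imprinted genes, at 0.937 for dorsoventral, axon guidance, cell cycle, complex I, proteasome and chromatin genes, at 0.935 for granule, Purkinje and neural crest genes, at 0.938 for signalling, at 0.934 for protocadherins and at -32.4 for cardiac genes. Direction turned at 0.934 for microglia, erythroid, hepatocyte, skeletal muscle, pluripotency and vomeronasal genes, at -0.540 for ribosomal proteins, -11.4 for histones, -3.84 for other-tissue factors and -0.115 for Zfp genes. The lists that turned at 0.934 have few CpG-rich members, from 0.306% of 327 vomeronasal genes to 12.5% of 16 pluripotency genes. Those turns therefore rest on very few genes. Breadth there lost its call for serotonergic genes (28.3) and chromatin regulators (8.36), and turned for forebrain factors (0.555), cell cycle (-1.16) and ribosomal proteins (-0.528). Y-linked genes, keratins and olfactory receptors gave no value in this setting.

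With only touching peaks joined, breadth lost its call for histones (1.78), mesenchyme (9.29) and imprinted genes (10.6), and turned for noradrenergic (-5.01), cell cycle (-5.02), ribosomal (-2.49), oligodendrocyte (-5.01), erythroid (14.9986) and pluripotency genes (9.28). With peaks under 3 kb apart joined it lost its call for noradrenergic genes (20.0), astrocytes (10.4), mesenchyme (9.29), imprinted genes (7.51) and chromatin regulators (8.90), and turned for forebrain factors (5.72), cell cycle (-1.89), choroid plexus (11.7), erythroid genes (14.9986) and protocadherins (12.1). For the broadest 10% it lost its call for serotonergic genes (23.3), histones (5.26), mesenchyme (18.6) and chromatin regulators (12.2), and turned for forebrain factors (4.28), cell cycle (-3.77), ribosomal proteins (-2.43), choroid plexus (23.3), erythroid (9.99), skeletal muscle (9.99) and pluripotency genes (4.27). Each domain counted once ended the call for histones (3.83) and brought mature channels past the test (9.66).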

Other observations

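The tests of explanations for breadth and for the marking of forebrain and midbrain factors were chosen after the results were seen, and the values on non-coding genes and summits were not tested. Non-coding genes more than 5 kb from a coding start carried the mark at class-dependent rates. Of such lincRNA genes 494 of 5188 were marked, 9.52% (8.75 to 10.4), and of antisense genes 144 of 1584, 9.09% (7.77 to 10.6). MicroRNA genes were marked in 76 of 1670, 4.55% (3.65 to 5.66), small nucleolar RNA genes in 3.37% and small nuclear RNA genes in 2.43%. Processed pseudogenes, at 1.45% (1.22 to 1.72), were lowest.

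Peak summits sat downstream of gene starts. At 2806 genes with a single annotated start the summit was downstream in 92.3% (91.3 to 93.2), at a median of 240 bp (interquartile range 154 to 386). Around those starts the peak reached a median of 580 bp upstream and 1384 bp downstream.

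No biological explanation was tested, since the design has 1 group. The broader domains of hindbrain patterning factors were set against 3 technical explanations. Peak strength was not among the 3. The median highest fold was 34.8 for hindbrain patterning factors and 10.2 for forebrain and midbrain factors. No setting matched the lists for strength, so it stays open. A CpG-rich 5'-most start as the whole cause is argued against, since among CpG-rich promoters the mean log2 difference was 2.80 (18 against 18 genes, permutation p = 2e-05, the smallest possible). Genes were not matched for CpG amount or for the length of CpG-rich sequence, so CpG content in that sense stays open. In that setting Hoxa1 to Hoxa4, which share the domain of 58302 bp, were counted as separate genes. Repeated counting of Hox genes in shared domains is argued against by 2.17 with each domain counted once, and a larger number of annotated starts by 2.83 with the 5'-most start only. That the difference follows which factors are active in hindbrain cells remains a hypothesis, found and tested on the same data and without expression measurements.

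The marking of all forebrain and midbrain factors, mostly with domains that were not broad, was weighed next. Promoters rich in CpG being marked whatever the lineage stays open. The 5 members with no CpG-rich start were marked in 100%, against 32.4% of 10908 other such genes, but that share was fixed once all members were known to be marked, so it decides nothing. Tissue carried over from the midbrain or forebrain also cannot be told apart from marking within hindbrain cells. Their highest fold differed from that of factors of non-brain tissues by a mean log2 of 0.0279 (95% bootstrap interval -0.47 to 0.54, 27 against 27 genes, leaving out the gene in both lists) and their breadth by 0.04 (permutation p = 0.875). They were marked in 27 of 27 against 27 of 34 (Fisher's exact p = 0.0144), but the first share is the pattern itself. The fold interval leaves room for a small excess, so carry-over is not excluded.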
